A study of Arabidopsis thaliana with 4 samples.

How the data were processed

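Whole seedlings of Arabidopsis thaliana were profiled on 4 ATH1 arrays, 2 of the wild type and 2 of flc-3, grouped by the genotype in the labels. The deposited values are signal intensities on a linear scale, made with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. MAS5 summarises the probe pairs of a probe set into 1 signal and scales each array. In the values, the mean after trimming 2% at each end was 100.01 on each array, so the deposited scaling was kept with no further normalization. Detection calls were not used here, so it is not known which signals lay above background, and differences of dim probe sets are the least certain.

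Of 22810 probe sets, 64 controls were left out. A platform annotation gave 1 gene symbol to 13513 of the other 22746 (59.4%), several to 503 and none to 8730. Symbols were updated through gene identifiers in a TAIR10.1 gene table, which gave a locus to 13436 probe sets. An unnamed probe set may still have a gene, and many genes of interest, FLC among them, are unnamed here. The values name no genome build, so no coordinates are given. Values were transformed as log2(value + 1), and fold changes are on that scale, which understates the change of dim probe sets. Probe sets with a mean below the 40th percentile were left out, leaving 13648, of which 7273 had a locus. Differences were tested, 2-sided, in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend, prior df 7.66, residual df 2), with genotype as the only term and Benjamini-Hochberg adjusted p under 0.05. Standard errors and p-values are moderated: the spread of each probe set is drawn towards that of other probe sets of like intensity. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

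Gene lists were tested with camera (preset correlation 0.01, and estimated), on 1 probe set per gene, the brightest with a single locus, where at least 5 members were tested. The fry test asked whether the genes of a list move, on balance, one way, without comparing them with other genes. The 16 main lists, and 21 gene families found by words in gene names, were fixed before the data were examined, as were the tests, the 2 chromosome intervals and the alternatives. A family is only what its words found: the words defensin or thionin caught mostly methionine genes, and the cytochrome P450 words also caught cyclophilins. The fixed lists hold 289 genes, of which 41 were named and 31 tested, so 2 of the 16 lists and 9 of the 21 families had enough members for a set test. The genes named in the text follow a fixed rule: FLC, the 15 largest differences in each direction among called probe sets with 1 locus and no overlap between genotypes, all members of a fixed list that passed over all genes or adjusted over the list alone, the 3 smallest p among its other members, and FRI, FT, SOC1, CCA1, LHY, TOC1, GI and LUX where measured. Other named genes, among them the examples from families and from lists written later, were chosen after their values were seen.

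The lists of LEA proteins, oleosins, seed cupins, and anthocyanin and flavonoid genes were written after the calls had been seen, from general knowledge of family and pathway membership, and so was the list of plastid genome loci. Fisher's exact tests of their share of calls used the 7208 tested genes with a locus as background. A further 3 lists written with them had fewer than 5 tested members and got no set test, and 2 families found by name were looked at as well. Their counts are in the closing observations.

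The intervals were loci AT4G00005 to AT4G03500 near FRI and AT5G09000 to AT5G11300 near FLC, with 4 Fisher's exact tests adjusted together. On simulated data with 13648 probe sets, 200 of them changed, 10 runs of the limma step recovered 89% of 2-fold and 99.8% of 4-fold changes with 5% false calls, and camera called 10 of 10 changed and 0 of 10 unchanged lists. Alternatives were 3 other normalizations, pseudocounts of 16 and 0.1, no filter and a filter at the 60th percentile, eBayes without the trend or robust, the replicate number as a block, other thresholds, an ordinary 2-sample test, estimated correlations, all probe sets of a gene, narrower intervals, and each array left out. The level of FLC, planned as a result of its own, is not reported.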

Results

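Transcript levels were measured with 4 Affymetrix ATH1 arrays, a 1-colour expression array for Arabidopsis thaliana, in whole seedlings of 2 genotypes in the Col-0 background, with 2 arrays per genotype. The wild type is labelled as carrying FRI and FLC, and the mutant flc-3 is labelled as a knockout of FLC (AT5G10140), which encodes a MADS-box repressor of flowering. The titles write the mutant in lower case as fri, so its FRI allele is not settled by the labels. Seedlings spent 6 days in constant light and 4 days in cycles of 12 h light and 12 h dark at 22 °C before they were moved to constant light at 27 °C, as the treatment text and the series title give it. A general temperature entry in the labels reads 22 °C, and the treatment text was followed. Each array carried a pool of RNA from 24, 30, 36 and 42 h after that move. Each value is therefore an average over a circadian cycle and carries neither phase nor period. The median signal was 47.2 and 47.3 in the wild-type arrays and 48.5 and 47.1 in the flc-3 arrays. Across probe sets, log2 signals correlated at r = 0.972 between the wild-type arrays, at 0.98 between the flc-3 arrays, and at 0.968 to 0.974 between arrays of different genotype. The number of arrays limits the precision of every value.

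The comparison of flc-3 with the wild type asked which transcripts differ at 27 °C when FLC is lost. Of the tested genes, 16 of 25 for late embryogenesis abundant (LEA) proteins, 5 of 5 for oleosins and 3 of 4 for seed cupins were higher in flc-3, and 5 of 7 for anthocyanin and flavonoid synthesis were lower, on lists written after the calls had been seen. Set tests of the LEA, oleosin and anthocyanin lists gave adjusted p = 0.0689 with an estimated correlation. The rises reached 10.9-fold for PAP85, a vicilin-type seed storage cupin, with signals of 63 and 39.5 in the wild type and 633 and 483 in flc-3 (log2 difference 3.44 ± 0.20, SE, n = 2 arrays per genotype, limma adjusted p = 2.76e-05). Among named genes the falls reached 4.78-fold for AT4G14090, an anthocyanin 5-O-glucosyltransferase, with signals of 235 and 158 in the wild type and 36.1 and 43.1 in flc-3 (log2 difference -2.26 ± 0.19, limma adjusted p = 0.000141). Of 13648 tested probe sets, 230 passed an adjusted p of 0.05 in limma, 187 of them higher in flc-3 and 43 lower. A change of at least 2-fold was seen in 122 of the higher and 16 of the lower probe sets. In all 230, both flc-3 arrays lay on the same side of both wild-type arrays, as did 43% of all tested probe sets, where chance gives 33.3%. With 1 named locus each, 109 of the higher and 24 of the lower probe sets could be described by gene. The count of 230 was 121 with no filter on dim probe sets, 149 with a stricter filter and 0 in an ordinary 2-sample test with Benjamini-Hochberg adjustment, where 1196 probe sets had an unadjusted p under 0.05. It was 147 without flc-3 replicate 1 and 364 without wild type replicate 1, and the 43 lower probe sets became 26 without flc-3 replicate 1, 24 without flc-3 replicate 2 and 74 without wild type replicate 1.

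**Figure D1:**
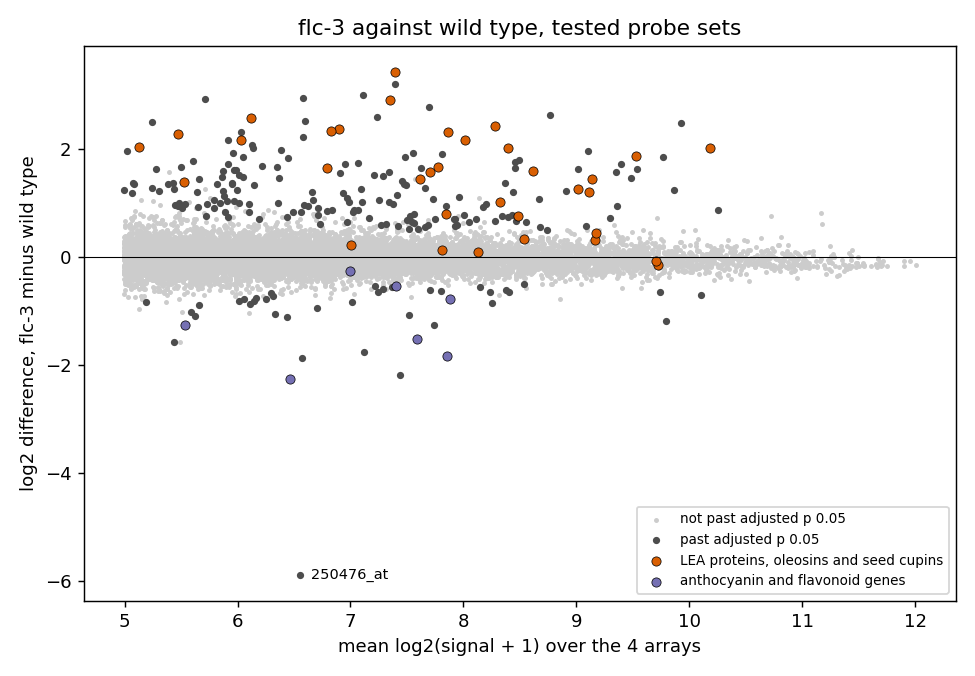
Each point is 1 of the 13648 tested probe sets, with its mean log2(signal + 1) over the 4 arrays on the horizontal axis and its log2 difference, flc-3 minus wild type, on the vertical axis. Dark points passed an adjusted p of 0.05, orange points are tested members of the 3 seed-related gene lists, of which 24 of 34 passed, and purple points are the 7 tested anthocyanin and flavonoid genes, of which 5 passed.

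No probe set is named as FLC in the annotation used here, so the level of the targeted gene is not reported and the genotype labels were not checked by it. The probe set with the largest difference, 250476_at, has no gene name in that annotation. Its signal was 775 and 680 in the wild type and 9.97 and 12.5 in flc-3, so that it fell by 5.90 on the log2 scale (SE 0.15, limma adjusted p = 6.79e-08). The size of this fall is uncertain, since both flc-3 signals lay below the 25th percentile of their arrays (13.8 and 13.2) and the difference was -4.77 with a pseudocount of 16. Of the 230 called probe sets, 97 had no single named locus, among them 246299_at with a log2 difference of 3.21 and 250868_at with 2.63.

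LEA proteins are hydrophilic proteins that accumulate as seeds dry. Of 25 tested LEA genes, 16 rose in flc-3, by 1.26 to 2.91 on the log2 scale, and none fell in limma at an adjusted p of 0.05. The largest rise was that of LEA (AT2G21490), a dehydrin, from 71.8 and 47.8 to 478 and 419. LEA4-5 (AT5G06760) rose by 2.43, AtLEA4-1 (AT1G32560) by 2.17 and AT3G02480 by 2.03, the last from 639 and 516 to 2370 and 2340. The LEA genes that did not pass included AT1G54410 at -0.14 and AT2G44060 at -0.08. All 5 tested oleosin genes, which encode the coat proteins of seed oil bodies, rose, by 1.03 to 2.29. OLEO3 (AT5G51210) went from 17.2 and 21.2 to 124 and 75.8, and AT3G01570 from 198 and 139 to 764 and 604. Of 4 tested seed cupin genes, PAP85, AT4G36700 (2.38) and AT2G28490 (1.21) rose, and AT1G07750 had a difference of 0.09. Calls made up 64% of the tested LEA genes against 1.63% of other tested genes (Fisher's exact test, 2-sided, adjusted p = 5.1e-22), and 100% of the oleosin genes against 1.78% (Fisher's exact test, adjusted p = 3.97e-09). The camera set tests gave adjusted p = 2.31e-38 for the LEA genes and 2.1e-14 for the oleosins with a preset correlation, and adjusted p = 0.0689 for each with an estimated correlation. The self-contained fry test gave an unadjusted p = 0.0124 for the LEA genes and 0.0188 for the oleosins. These 3 lists were written after the calls had been seen, so they are not independent evidence of the enrichment or of the direction. Fisher's exact test also treats genes as independent, while the estimated correlation was 0.46 within the LEA list and 0.61 within the oleosins. Without flc-3 replicate 1, only 3 oleosin genes lay above the filter on dim probe sets, and all 3 passed. With no filter, the oleosin AT2G25890 (adjusted p = 0.0861), the cupin AT2G28490 (0.0501) and the LEA gene AT4G39130 (0.0501) lost their calls.

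The seed-related genes also differed between arrays of 1 genotype. Of the 34 tested members of the 3 lists, 29 were higher in wild type replicate 1 than in replicate 2, with a median log2 difference of 0.30, and 28 were higher in flc-3 replicate 1 than in replicate 2, with a median of 0.21. Over all tested probe sets those medians were -0.01 and 0.01. The difference between the genotypes was larger, with a median of 1.58 and 32 of the 34 members above 0.

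Of the 15 named genes with the largest rises, 8 belong to those 3 lists: PAP85, LEA, AT5G44310 (2.58), LEA4-5, AT4G36700, AT2G23110 (2.34), AT4G36600 (2.32) and OLEO3. Outside them, ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle that turns stored lipid into sugar, rose by 2.48 ± 0.16 (SE), from 477 and 356 to 2110 and 2490 (limma adjusted p = 3.87e-05). AT2G47780 rose by 3.00, from 51.6 and 44.6 to 407 and 376. AT5G44440, of the berberine bridge enzyme-like family, rose by 2.93, and AT5G66780 by 2.78. The remaining 3 were AT1G15330 (2.59), AT1G48660 (2.51) and AT1G33790 (2.32), a jacalin-like lectin gene. Standard errors of the 15 rises lay between 0.12 for AT2G47780 and 0.24 for OLEO3. None of the 15 lost its call in those of the 14 alternative limma fits in which it was tested. Of the 15, 10 were tested in all 14 fits, and the others, which fell below the filter in some, in 11 to 13. The ordinary 2-sample test called 0 probe sets after adjustment, so there all 15 lost their call. With a pseudocount of 16 the folds of 3 genes with dim wild-type signals moved by over 1.5 times, to log2 differences of 2.23 for AT5G44440, 1.77 for AT1G48660 and 1.69 for OLEO3. A further regulator, chosen after its value was seen, was EEL (AT2G41070), a bZIP transcription factor of seed maturation, which rose by 1.63 from 27 and 16.4 to 81 and 55.9.

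**Figure D2:**
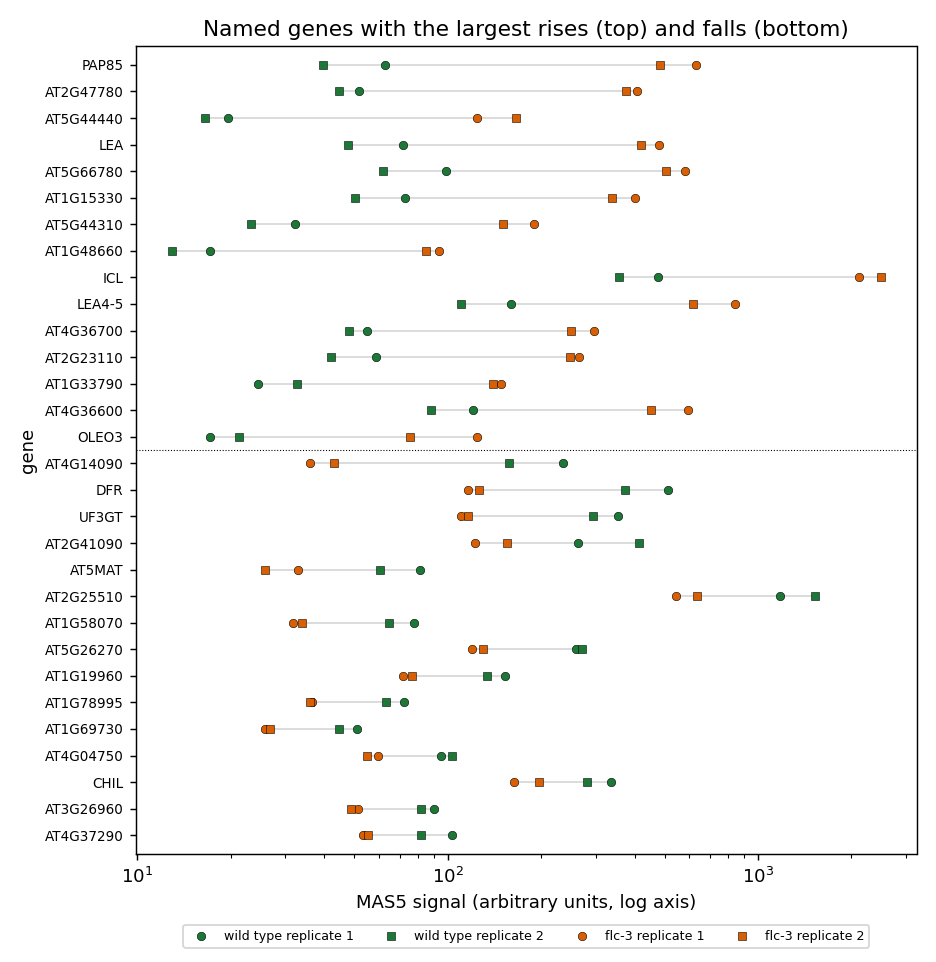
MAS5 signal on each of the 4 arrays (log axis) for the 15 named genes with the largest rises (top) and the 15 with the largest falls in flc-3 (bottom), with circles for replicate 1 and squares for replicate 2. By the rule that picked the genes, the green wild-type points and the orange flc-3 points of each gene do not overlap. They run from 39.5 and 63 against 483 and 633 for PAP85 to 82.2 and 103 against 53.3 and 55.5 for AT4G37290.

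Genes of anthocyanin synthesis, the pathway to red and purple flavonoid pigments, made up 4 of the 5 largest falls among probe sets with a named gene. DFR (AT5G42800), dihydroflavonol reductase, fell by 1.84 ± 0.15 on the log2 scale (SE), from 513 and 372 to 116 and 126 (limma adjusted p = 9.64e-05). UF3GT (AT5G54060), which adds a sugar to anthocyanins, fell by 1.51, from 355 and 293 to 110 and 116. AT5MAT (AT3G29590), an anthocyanin malonyltransferase, fell by 1.25, and CHIL (AT5G05270), a chalcone isomerase-like gene, fell by 0.77. With AT4G14090, 5 of 7 tested anthocyanin and flavonoid genes fell, and the flavonoid glycosyltransferase genes UGT78D2 and UGT78D1 had differences of -0.53 (limma adjusted p = 0.123) and -0.25. That is 71.4% of the list against 1.78% of other tested genes (Fisher's exact test, 2-sided, adjusted p = 5.39e-08). The camera set test gave adjusted p = 3.98e-14 with a preset correlation and adjusted p = 0.0689 with an estimated correlation, and fry gave an unadjusted p = 0.0166. This list too was written after the calls had been seen and is not independent evidence. CHIL lost its call without flc-3 replicate 1 (adjusted p = 0.146) and AT5MAT without flc-3 replicate 2 (adjusted p = 0.0506), both lost it with no filter on dim probe sets, and UGT78D2 passed without wild type replicate 2 (adjusted p = 0.0137).

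The other 10 of the 15 largest named falls lay outside the anthocyanin and flavonoid list. AT2G41090, a calmodulin-like gene, fell by 1.26, from 263 and 413 to 122 and 155, and AT2G25510 fell by 1.19, from 1180 and 1520 to 544 and 634. AT1G58070 and AT5G26270 fell by 1.09 and 1.08, AT1G19960 by 0.94 and AT1G78995 by 0.89. AT1G69730, of the wall-associated kinase family, fell by 0.84, AT4G04750, a sugar transporter-like gene, by 0.78, AT3G26960 by 0.77 and AT4G37290 by 0.75. Leaving out 1 array ended the call of 7 of the 15 falls in at least 1 case. Besides CHIL and AT5MAT, AT1G69730, AT1G78995, AT3G26960 and AT4G37290 lost it without flc-3 replicate 1, flc-3 replicate 2 or wild type replicate 1, with log2 differences of -0.59 to -0.90, and AT4G04750 lost it without flc-3 replicate 1, flc-3 replicate 2 or wild type replicate 2, with -0.72 to -0.84. AT1G69730 and AT4G37290 also lost it under cyclic loess (adjusted p = 0.068 and 0.0651) or quantile normalization (0.0704 and 0.073), AT1G69730 under robust eBayes (0.0504), and AT4G37290 and CHIL without the intensity trend (0.066 and 0.0712). With no filter on dim probe sets, 7 of these 10 lost their call: AT2G41090 (adjusted p = 0.0994), AT1G58070 (0.0658), AT1G78995 (0.103), AT1G69730 (0.201), AT4G04750 (0.0696), AT3G26960 (0.0938) and AT4G37290 (0.143).

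Of the 33 genes of the circadian clock list, 5 were tested in these pooled samples, and none passed an adjusted p of 0.05 over all genes in limma. FIO1 (AT2G21070), whose loss lengthens the circadian period, passed when adjusted over the list alone, with a log2 difference of 0.85 ± 0.20 (SE) and limma adjusted p = 0.0803 over all genes. FIO1 signals were 28.2 and 21.1 in the wild type and 47.4 and 42 in flc-3, and it passed over all genes without wild type replicate 1 (adjusted p = 0.0255). GI, a clock and flowering-time gene, had a difference of 0.12, from 97.2 and 113 to 119 and 109, RVE6 one of 0.10 and TIC one of -0.10. The list had a median of 0.10 and a camera adjusted p = 0.239 with a preset correlation, and fry gave an unadjusted p = 0.121. RCA, Rubisco activase, the 1 tested clock output gene, had a difference of -0.15.

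Of 5 tested cold and dehydration genes, COR15A, COR47 and LTI30, which encode protective hydrophilic proteins, passed when adjusted over the list alone and none passed over all genes in limma. Their differences were 0.80, 0.32 and 0.34, and those of COR15B and STZ were 0.14 and -0.17. COR15A signals were 182 and 166 in the wild type and 408 and 225 in flc-3, and it passed over all genes without flc-3 replicate 2 (adjusted p = 0.000745). The list had a median of 0.32 and a camera adjusted p = 0.0282, and adjusted p = 0.342 with an estimated correlation, and fry gave an unadjusted p = 0.218. Its camera call was also lost without flc-3 replicate 1 (adjusted p = 0.133), wild type replicate 1 (0.0547) or wild type replicate 2 (0.14). COR15A, COR15B, COR47 and LTI30 also stand in the LEA list.

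Flowering-time genes were thinly covered. Of the floral integrators and targets only SMZ and SNZ, both AP2-type floral repressors, were tested, with differences of -0.19 and 0.06. Of the FLC regulators, FY, an RNA 3′ processing factor, had a difference of -0.64 and passed when adjusted over the list alone, and LD had 0.12. FRI, FT, SOC1, CCA1, LHY, TOC1 and LUX have no named probe set in the annotation used here. Of the root markers, EXPA7, a root hair expansin, had a difference of 0.69 and passed when adjusted over the list alone, and EXPA18 and PYK10 had 0.34 and -0.09, the latter 0.04 after quantile normalization. The light harvesting list had a median of -0.15 over 4 tested genes, with LHCB4.2 at -0.20, LHCB4.1 at -0.15 and LHCB4.3 at -0.10. The heat shock list had a median of 0.00 over 4 genes, with HSA32 at -0.38, ROF2 at 0.05 and ATHSP22.0 at 0.06. The gibberellin list had a median of 0.09 over 4 genes, with GID1C at 0.28, GID1A at 0.21 and SPY at -0.04. IAA29, the 1 tested gene of warm-temperature growth, had -0.14, and HYH, the 1 tested light-signalling gene, had -0.01. None of these genes passed over all genes in limma, which called 230 probe sets and gave an unadjusted p under 0.05 to 1646. The lists of FLC relatives, floral organ identity, shoot meristem, pathogen response, and seed storage and oil bodies had 0 tested members. Of 9 gene families with at least 5 tested members, none passed in camera, which tests for a shared direction, with adjusted p from 0.481 to 0.932. In 1 of the 9, found by the words defensin or thionin, 13 of 15 tested members were caught inside longer words such as methionine, and without it the other 8 gave adjusted p from 0.427 to 0.932. When adjusted over the family alone, members passed in both directions in 2 families, in 5 of 11 expansins (EXPA20 at 0.71, EXLB1 at -0.40) and 4 of 7 xyloglucan genes (XTH16 at 0.85, XTH20 at -0.78). The mixed fry test, which counts either direction and makes no comparison with other genes, passed in 5 of the 8 families, with adjusted p = 0.00628 for the expansins and 0.00808 for the xyloglucan genes.

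Loci near FRI and near FLC were compared with the other tested loci, since the lines may differ around these genes. Only probe sets with a named locus could be placed. The 97 called probe sets without one, 250476_at among them, were counted neither in the intervals nor elsewhere. Some of them may lie near FRI or FLC. Near FLC, 2 of 58 tested probe sets passed, AT5G10740 with a log2 difference of 1.00 and AT5G10120 with 0.71, a share of 3.45% against 1.79% elsewhere (Fisher's exact test, 2-sided, p = 0.281, adjusted over 4 tests 0.375). Near FRI, at the top of chromosome 4, 0 of 102 tested probe sets passed in limma against 1.83% elsewhere (Fisher's exact test, p = 0.266, adjusted 0.375). At an unadjusted p under 0.01 there were 10 near FRI, 9.8% against 4.5% elsewhere (Fisher's exact test, p = 0.026, adjusted 0.104), and 3 near FLC, 5.17% against 4.57% (p = 0.748). None of these 4 shares passed after adjustment in this fit. The result near FRI turned when the replicate number was added as a block, in a fit whose p-values are not reliable, as given with the alternatives below.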

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

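The control probe set for 25S ribosomal RNA, which entered no comparison, read 1426 in flc-3 replicate 1 against 134.6 in wild type replicate 1, 47.6 in wild type replicate 2 and 45.7 in flc-3 replicate 2. It was picked out because it is a signal outside the tested probe sets that lay above its level in the wild-type arrays.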

How the results depend on the processing

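The 15 largest rises and 15 largest falls kept their direction in each alternative in which they were tested, but counts of calls moved. With 1 array left out their direction could not have changed, since these genes were picked for no overlap between genotypes. The LEA, oleosin, seed cupin, anthocyanin and plastid lists were chosen after seeing the data, as were the window count near FRI, the tests of explanations and the other splits of the arrays. The alternatives named here were planned. Totals, higher and lower probe sets were 121, 107 and 14 with no filter on dim probe sets, 149, 118 and 31 with a filter at the 60th percentile, 0, 0 and 0 with an ordinary 2-sample test (1196 at an unadjusted p under 0.05), 633, 402 and 231 at an unadjusted p under 0.01, and 97, 89 and 8 for a 2-fold difference in all 4 pairs of arrays; 79 were lower at an adjusted p under 0.1. The number of probe sets tested changed with the filter, and the other causes were not tested. The replicate numbers pair nothing in the labels, and deviations of same-numbered arrays correlated at r = 0.09; with the replicate number as a block the counts were 769, 489 and 280, all 230 calls were shared, 15 plastid genes were called, and the share called near FRI turned from below to above the rest, at 15.69% against 5.52% (Fisher's exact test, p = 0.000175), with a window count of 22 near FRI. Leaving out 1 array, where the lone array of a genotype is assumed to vary like the other group, gave 147 to 364 calls, 121 to 290 higher and 24 to 74 lower; of the 230 calls, 133 were shared without flc-3 replicate 1. Called oleosins were 3 to 5 and called plastid genes 2 to 8 when 1 array was left out. With no filter, 3 anthocyanin and 0 plastid genes were called, and 3 oleosins at the 60th percentile. Without flc-3 replicate 1 the 3 called oleosins were the only ones tested. With an estimated correlation, set tests of the anthocyanin (median -1.25), LEA (1.44) and oleosin (2.02) lists gave adjusted p = 0.0689, the plastid list (0.10) 0.397 and the cold and dehydration list (0.32) 0.342. Leaving out 1 array, the median of the cold and dehydration list was 0.23 to 0.44 and that of the plastid list -0.03 to 0.24. Lists left with fewer than 5 tested members under an alternative, such as the oleosins without an flc-3 array, got no set test there. The ordinary 2-sample test called 0 probe sets, so no gene kept its call there. In the alternative limma fits none of the 15 largest rises lost its call where it was tested, in 11 to 14 alternatives each. Of the 15 largest falls, 9 lost it, all 9 with no filter. Over 86 single genes followed through those fits, 36 values lost their call and 13 gained one. The sign changed for 14 of these genes in at least 1 alternative, none of them past adjusted p 0.05 on all arrays and all within 0.15 of 0 on the log2 scale. The level of FLC was not run under any alternative, and dim signals cannot be set against background without detection calls.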

Other observations

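Of the tests below, those of the seed-related and anthocyanin genes, the windows near FRI, the plastid genes and the other splits of the arrays were chosen after the results had been seen, with the bounds that decide them. The plastid-encoded ATP synthase genes atpA and atpF, neighbours in 1 plastid gene cluster, rose by 1.24 and 1.21 on the log2 scale, atpA from 512 and 720 to 1660 and 1240 (limma adjusted p = 0.00816). The other tested ATP synthase genes of the plastid did not pass, with atpH at 1.1 (limma adjusted p = 0.0728), atpB at -0.02 and atpE at -0.12. The ribosomal protein gene rpl36 rose by 0.80. These were the 3 called genes of 66 tested plastid loci, 4.5% against 1.82% of other genes (Fisher's exact test, adjusted p = 0.122). The list had a median of 0.10, a camera adjusted p = 0.00159, and adjusted p = 0.397 with an estimated correlation. Without wild type replicate 1 the median was -0.03 (adjusted p = 0.943), and 7 genes were called without flc-3 replicate 2 and 8 without wild type replicate 2. With no filter on dim probe sets 0 plastid genes were called in limma.

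Of 7 tested xyloglucan family genes, XTH19 rose by 0.88 and XTH32 fell by 0.61, and the share of calls did not pass after adjustment over the families (Fisher's exact test, adjusted p = 0.0601). Among seed-related genes outside the lists, BETA-VPE, a vacuolar processing enzyme of seed storage proteins, rose by 0.65. The smaller lists written with the seed lists gave ICL at 2.48 and SDP1, a seed lipase, at 0.03 for 2 tested genes of lipid breakdown, EEL at 1.63 for 1 tested regulator of seed maturation, and PUB19 at 0.43 (limma adjusted p = 0.227) for 1 tested gene of the vegetative abscisic acid response. Genes found by the name LEA or dehydrin, a pattern that also caught unrelated genes such as LBD16, had 4 called of 10 tested and a median of 0.09, and OLEO3 was the 1 gene found by the name oleosin.

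The rise of seed-related genes in flc-3 was set against 3 explanations. A single deviating array would not set both flc-3 arrays apart from both wild-type arrays. The seed lists were written after the calls, and in every call both flc-3 arrays lay on the same side of both wild-type arrays. Over the 32 genes tested with and without flc-3 replicate 1, the median log2 difference was 1.51 with it and 1.42 without it. The rise of the listed genes was thus also present in flc-3 replicate 2, which their selection made likely. The other arrays left out gave medians of 1.41 to 1.68 over 33 or 34 genes. For the listed genes these values argue against a single deviating array as the whole cause. Because of how the lists were made, they do not show this for other seed-related genes. A general cold and dehydration response of seedlings is left open: the fixed list of 5 such genes had a median of 0.32, beside 1.66 for the seed lists without them, but the seed lists were written after their rises were seen and COR15A reached 0.80. More seed or embryo material in the flc-3 samples, for instance from late or failed germination, stays open and cannot be told apart from a change within seedlings, because 0 of the 10 genes of the fixed seed storage and oil body list are named. An effect of FLC on seed gene expression or germination may also account for it and was not tested.

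Of the 23 genes of the fixed light harvesting and Rubisco list, 4 were tested. They had a median of -0.15, from -0.10 to -0.20 with SEs of 0.12 to 0.20. The anthocyanin list, written after its falls were seen, had -1.25. LHCB4.1, LHCB4.2 and RCA lay high in the range, at 1890 to 3210 where array maxima were 3388.9 to 4745.8, and LHCB4.3 lay at 102 to 117. A dilution of green tissue RNA would lower them alike. As far as these 4 genes show, this argues against a smaller share of green seedling RNA as the whole cause. Under 3 other normalizations the weakest median of the anthocyanin list was -1.24, which argues against array scaling. An effect of the genotype, and a difference in age or growth between the seedlings, stay open and were not tested.

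A difference between the lines around FRI was examined because the titles write the mutant as fri. The 10 probe sets near FRI with an unadjusted p under 0.01, 8 higher and 2 lower, were set against 6702 overlapping windows of 102 neighbouring tested loci. The median window held 5 and 24 windows held at least 10, which puts the number near FRI at percentile 99.6. Neighbouring windows share nearly all their loci, and the 24 include the interval itself and may include its shifted copies. The percentile is therefore less precise than 6702 separate windows would make it. That window count was added after the 10 had been seen. The planned Fisher's exact test did not pass after adjustment (0.104), and 0 of 102 probe sets with a named locus passed an adjusted p of 0.05. Called probe sets without a name, such as 255676_at, have numbers within the range seen near FRI, so this 0 does not argue against a difference. The fit with the replicate number as a block, given above, had a larger share called near FRI than elsewhere, but its p-values are not reliable. A difference between the lines around FRI may exist but is left undecided. The smallest p in the interval belonged to AT4G01395, with a log2 difference of 0.58.

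The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. The genotype split gave 230 calls, and 1 of the 3 splits gave as many. The highest of the other splits gave 0 calls in limma, with 381 probe sets at an unadjusted p under 0.05.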
